A study of Homo sapiens with 6 samples.

How the data were processed

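RNA of 786-O cells was analysed in 6 libraries: 2 with a non-targeting control siRNA (NTC), 2 with ALYREF siRNA5 and 2 with ALYREF siRNA8. Per the labels, cells grew in RPMI with 10% FBS, were split into fresh medium 24 h after transfection and were harvested at 48 h. Per the labels, polyadenylated RNA went through double poly-dT selection into directional libraries, read as paired ends of 42 nt on an Illumina NextSeq instrument. The submitters' notes name STAR, Picard, HTSeq and DESeq2, without versions or settings, and the genome build hg19.

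The deposited files were 2 tables of the authors' results, 1 per siRNA, with 11681 rows each: 11679 gene symbols and the HTSeq counters for reads without a feature and for ambiguous reads. Per the file headers, the signal of each row is a mean normalized count over the libraries of the authors' DESeq2 fit, and it was identical in both tables, so that 1 fit covered all libraries. Per the file headers, the authors gave each fold change and its standard error as log2 values, and whether that fit used a prior that shrinks fold changes is not stated in the sources used here. The Wald score per the file headers is the log2 fold change divided by its standard error, which was checked on the authors' values. The authors' deposited p-values are normal and two-sided, and their adjusted p-values are Benjamini-Hochberg values over all rows, which was recomputed from the tables to within rounding. The direction, knockdown over control, was read from ALYREF, which is negative in both tables. Each table was assigned to its siRNA by the number shared by its file name and the library titles. The plan fixed before the data were examined assumed counts per library and a fit of its own, so here the authors' fit stands in its place, with 0.05 as the threshold on the authors' adjusted p-values.

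The mean per gene was 11.6 or more in both tables, and a filter on low counts is not stated in the sources used here. The reads without a feature made up 6.23% and the ambiguous reads 1.62% of the sum of all means, 13708491. Their log2 changes were 0.04 and -0.01 with siRNA5 and 0.08 and 0.01 with siRNA8 in the authors' deposited tables, and none passed the threshold (smallest adjusted p = 0.0669). The 10 most abundant genes held 3.69% of the sum of gene means. Rebuilt from the deposited standard errors, the spread between libraries beyond counting error had a median of 3.56% for the 3302 genes with a mean of at least 1000. The p-values measure only the spread between these libraries, which may be technical.

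The siRNAs were compared by the difference of their log2 fold changes over the root of the summed squared standard errors, with a normal two-sided p and Benjamini-Hochberg adjustment over the genes. This test was added after the tables were seen. It leaves out the covariance from the shared controls, so its standard error is an upper bound, and an alternative rebuilt the control variance from the tables. Overlaps were set beside the number for independent lists of the same sizes, and beside 100 simulated data sets with shared controls and no effect.

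Before the data were examined, 26 gene lists were fixed. They cover TREX and mRNA export factors, nuclear speckle proteins, exon junction complex and NMD factors, transcripts targeted by NMD, HIF-2 targets, glycolysis enzymes, E2F targets and DNA replication, G2 and mitosis, and homologous recombination and Fanconi anaemia. They also cover p53 targets, ATF4 and amino acid response, ER chaperones and the unfolded protein response, cytosolic heat shock proteins, interferon-stimulated genes, NF-kB and inflammatory genes, extracellular matrix and integrins, and cholesterol synthesis. The last are cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, mitochondrially encoded genes, intronless protein-coding genes, nuclear-retained long non-coding RNAs, and markers of proximal tubule, immune, endothelial and keratin-rich epithelial cells. The 23 lists with at least 5 measured members were tested with cameraPR (limma 3.58.1, R 4.3.3) on ranks of the authors' Wald statistic, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test on the statistic of the difference compared the siRNAs. An estimated correlation needs values per library, so a preset of 0.05 was used beside it. Random lists matched on mean level were a further alternative. They draw genes independently, so they make no allowance for correlation between genes, and their p-values can be too small for members that vary together.

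Genes were named by a rule fixed before the data were examined, which took 114 genes. It takes ALYREF, the 5 largest rises and falls per siRNA and per direct comparison, and the 10 largest rises and falls in one direction with both siRNAs, all in the upper part of genes by mean level. It further takes up to 2 rises and 2 falls per list, and SON, SRRM2, EPAS1, VHL, THOC1, NXF1, MALAT1, GAPDH and ACTB. The rule's demand that both treated libraries lie beyond both controls could not be applied without values per library. A further 16 genes were added as examples after their values were seen. XIST and Y-linked genes were left out of the named genes.

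Transcript sequence, GC content, length and exon number came from GENCODE release 29 by gene symbol, for 11024 genes (94.4%), and a heptamer scan of 3' UTRs regressed each log2 fold change on UTR length and composition. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The procedure was tested on simulated data with 100 changed genes among 11679: the control comparison recovered 64% of 1.5-fold and 84% of 2-fold changes with 6 unchanged genes called, and the direct comparison recovered 51% and 75% with 0 called. A planted list of 30 genes shifted by 0.2 gave adjusted p = 0.0311 with 0 of 100 unchanged lists called, and a planted heptamer ranked 1. The simulated genes varied independently of each other, so the list result says nothing about false calls for lists whose members vary together. Alternatives were stricter thresholds, a mean of at least 50, a repeat without the counters, centred fold changes, other list tests and a repeat without genes holding the heptamers. Sequencing reads were not used here.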

Results

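Polyadenylated RNA was sequenced from 786-O cells, a human clear cell renal cell carcinoma line. ALYREF, an adaptor that links the packaging of messenger RNA in the nucleus to its export, was knocked down with 2 different siRNAs, named siRNA5 and siRNA8 after the numbers in the library titles. A non-targeting siRNA served as the control. The 6 libraries formed 3 groups of 2 duplicates, harvested 48 h after transfection. The authors' deposited tables held 11679 genes, each with 1 mean normalized count over the libraries of the fit and a fold change against the control for each siRNA. These gene means had a median of 459 and summed to 12632521 normalized counts, and the depth of each library is not given in the sources used here. The median standard error of a log2 fold change in the authors' deposited tables was 0.44 for the 1423 genes with a mean under 50 and 0.073 for the 5538 genes with a mean of 500 or more with siRNA5. Fold changes below are log2 values against the control with their standard errors (SE), and a gene was called at an adjusted p under 0.05.

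The first question was whether both siRNAs lowered their target. ALYREF, with a mean of 2917 normalized counts, fell by 4.14 (SE 0.096) with siRNA5 and fell by 3.67 (SE 0.085) with siRNA8 in the authors' deposited tables. This left 5.67% of the control level with siRNA5 (95% interval 4.98 to 6.46) and 7.83% with siRNA8 (95% interval 6.98 to 8.79), by the authors' deposited tables. ALYREF was 17.6-fold lower with siRNA5 and 12.8-fold lower with siRNA8, and both adjusted p-values are listed as 0 in the authors' deposited tables. The fall was deeper with siRNA5 by a log2 difference of -0.47 (SE 0.13, adjusted p = 0.00152).

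The comparison of siRNA5 with the control asked which transcripts changed after loss of ALYREF. Among genes in the upper part by mean level, from which the leading genes of each comparison were taken, H2AFX and H1FX were among the deepest falls. H2AFX, which encodes the DNA damage histone H2AX, fell 3.62-fold (log2 -1.85, SE 0.073, adjusted p = 1.01e-140), and H1FX, a linker histone, fell 3.99-fold (SE 0.13 on the log2 scale, adjusted p = 6.33e-52) in the authors' deposited table. C11orf68 fell 4.72-fold (log2 -2.24, SE 0.11) and TRNP1, a nuclear protein, fell 4.13-fold (log2 -2.04, SE 0.12) in the authors' deposited table. IL1RAP, the accessory chain of the interleukin-1 receptor, rose 4.49-fold (log2 2.17, SE 0.11), and TMEM2, a cell-surface hyaluronidase, rose 4.31-fold (log2 2.11, SE 0.056) in the authors' deposited table. PLAU, the urokinase plasminogen activator, rose 3.42-fold (log2 1.77, SE 0.069), the mRNA decapping enzyme DCP2 rose 3.01-fold (log2 1.59, SE 0.084) and the zinc-finger gene ZNF367 rose 2.97-fold (log2 1.57, SE 0.068) in the authors' deposited table. By the authors' deposited adjusted p-values, 2852 genes were higher and 2571 were lower than in the control, which together are 46.4% of the genes. Most of these changes were small: the median absolute log2 change of the called genes was 0.42, or 1.34-fold, and 193 genes rose and 363 fell by at least 2-fold.

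Mitotic genes rose as a group with siRNA5. Of the 40 measured G2 and mitosis genes, 24 rose, 5 fell and 11 were not called (25 and 7 adjusted over the list alone), with a median log2 change of 0.20. The list test gave adjusted p = 0.00238. It gave adjusted p = 0.0669 with a preset correlation of 0.05, which ends the call. On log2 fold changes without ranks, in place of ranks of the Wald statistic, it gave adjusted p = 0.128, which also ends the call. MKI67, the Ki-67 proliferation marker, rose by 0.43 (SE 0.066), CCNA2, cyclin A2, rose by 0.47 (SE 0.047) and CENPF, a kinetochore protein, rose by 0.56 (SE 0.075) in the authors' deposited table, and these examples were chosen after their values were seen. FOXM1, a transcription factor of mitotic genes, fell by 0.83 (SE 0.057) in the authors' deposited table. Of the 20 genes for ER chaperones and the unfolded protein response, 12 rose, 2 fell and 6 were not called (12 and 2 adjusted over the list alone), with a median of 0.21. Their list test gave adjusted p = 0.00238, adjusted p = 0.0614 with the preset correlation of 0.05, adjusted p = 0.114 on log2 fold changes and adjusted p = 0.0506 against random lists matched on mean level, so each of these settings ends the call. DNAJB9, an ER co-chaperone, rose by 1.06 (SE 0.13) and EDEM1, which acts in ER-associated degradation, rose by 0.46 (SE 0.080), while SDF2L1, an ER-resident chaperone cofactor, fell by 0.32 (SE 0.11) in the authors' deposited table.

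Inflammatory genes also rose with siRNA5, and p53 targets fell. Of the 22 measured NF-kB and inflammatory genes, 12 rose, 1 fell and 9 were not called (12 and 1 adjusted over the list alone), with a median of 0.66. The list test gave adjusted p = 0.00646, and adjusted p = 0.0669 with the preset correlation of 0.05, which ends the call. The leukocyte adhesion receptor ICAM1 rose by 0.93 (SE 0.061) and the cytokine CSF2 by 2.12 (SE 0.32) from a low mean of 42.7 in the authors' deposited table, 2 genes chosen after their values were seen. The apoptosis inhibitor BIRC3 rose by 0.70 (SE 0.079) and TNFAIP2 fell by 0.48 (SE 0.077) in the authors' deposited table. Of the 23 measured p53 targets, 13 fell, 1 rose and 9 were not called (14 and 1 adjusted over the list alone), with a median of -0.28. Their list test gave adjusted p = 0.0026, and adjusted p = 0.0669 with the preset correlation of 0.05, which ends the call. CDKN1A, the cell cycle inhibitor p21, fell by 1.24 (SE 0.10) in the authors' deposited table and was chosen after its values were seen. CCNG1, cyclin G1, fell by 0.87 (SE 0.077) and TNFRSF10B, a death receptor, rose by 0.36 (SE 0.058) in the authors' deposited table. The correlation between genes could not be estimated for any list, because that needs values per library, so the preset 0.05 stands in its place.

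The comparison of siRNA8 with the control asked the same question. COX7C, a subunit of cytochrome c oxidase, fell 5.68-fold (log2 -2.51, SE 0.11, adjusted p = 3.13e-114) in the authors' deposited table, while its log2 change with siRNA5 was -0.05 (SE 0.081). LSM14B, an RNA-binding protein, fell 3.97-fold (log2 -1.99, SE 0.092), SYPL1, a vesicle membrane protein, fell 3.78-fold (log2 -1.92, SE 0.063) and TWF1, an actin-monomer-binding protein, fell by 1.86 (SE 0.081) in the authors' deposited table. HMOX1, heme oxygenase 1, rose 3.70-fold (log2 1.89, SE 0.14) and CD274, the immune checkpoint ligand PD-L1, rose 3.51-fold (log2 1.81, SE 0.10) in the authors' deposited table. TMEM2 rose 3.08-fold (log2 1.62, SE 0.056), and the MAP kinase phosphatases DUSP10 and DUSP5 rose by 1.56 (SE 0.095) and 1.53 (SE 0.12) in the authors' deposited table. By the authors' deposited adjusted p-values, 2458 genes were higher and 2389 were lower, 41.5% of all genes. The median absolute log2 change of the called genes was 0.41, or 1.33-fold, and 183 genes rose and 320 fell by at least 2-fold.

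DNA replication genes fell as a group with siRNA8. Of the 44 E2F target and DNA replication genes, 28 fell, 2 rose and 14 were not called (28 and 2 adjusted over the list alone), with a median of -0.21 and a list test adjusted p of 8.59e-06. This call held with the preset correlation of 0.05 (adjusted p = 0.0126) and was lost on log2 fold changes (adjusted p = 0.171). GINS2, part of the replicative helicase, fell by 0.99 (SE 0.078), while the polymerase subunit POLD1 rose by 0.35 (SE 0.075) in the authors' deposited table. Of the 40 G2 and mitosis genes, 22 fell, 4 rose and 14 were not called (23 and 4 adjusted over the list alone), with a median of -0.15. The list test gave adjusted p = 0.00293, adjusted p = 0.106 with the preset correlation of 0.05 and adjusted p = 0.655 on log2 fold changes, so both settings end the call. The spindle kinase AURKA fell by 0.44 (SE 0.047) and the mitotic kinase CDK1 rose by 0.32 (SE 0.051) in the authors' deposited table. Of the 22 measured cholesterol synthesis genes, 11 fell, 0 rose and 11 were not called (11 and 0 adjusted over the list alone), with a median of -0.29. Their list test gave adjusted p = 0.00293, adjusted p = 0.0606 with the preset correlation of 0.05 and adjusted p = 0.169 on log2 fold changes, so both settings end the call. The sterol enzymes LSS and FDFT1 fell by 0.92 (SE 0.11) and 0.42 (SE 0.093), and MSMO1, a sterol enzyme chosen after its values were seen, fell by 1.53 (SE 0.10) in the authors' deposited table. MSMO1 holds in its 3' UTR a heptamer that went with lower levels under siRNA8, and without genes holding it or a like heptamer found for siRNA5 the list test gave adjusted p = 0.0385.

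**Figure D1:**
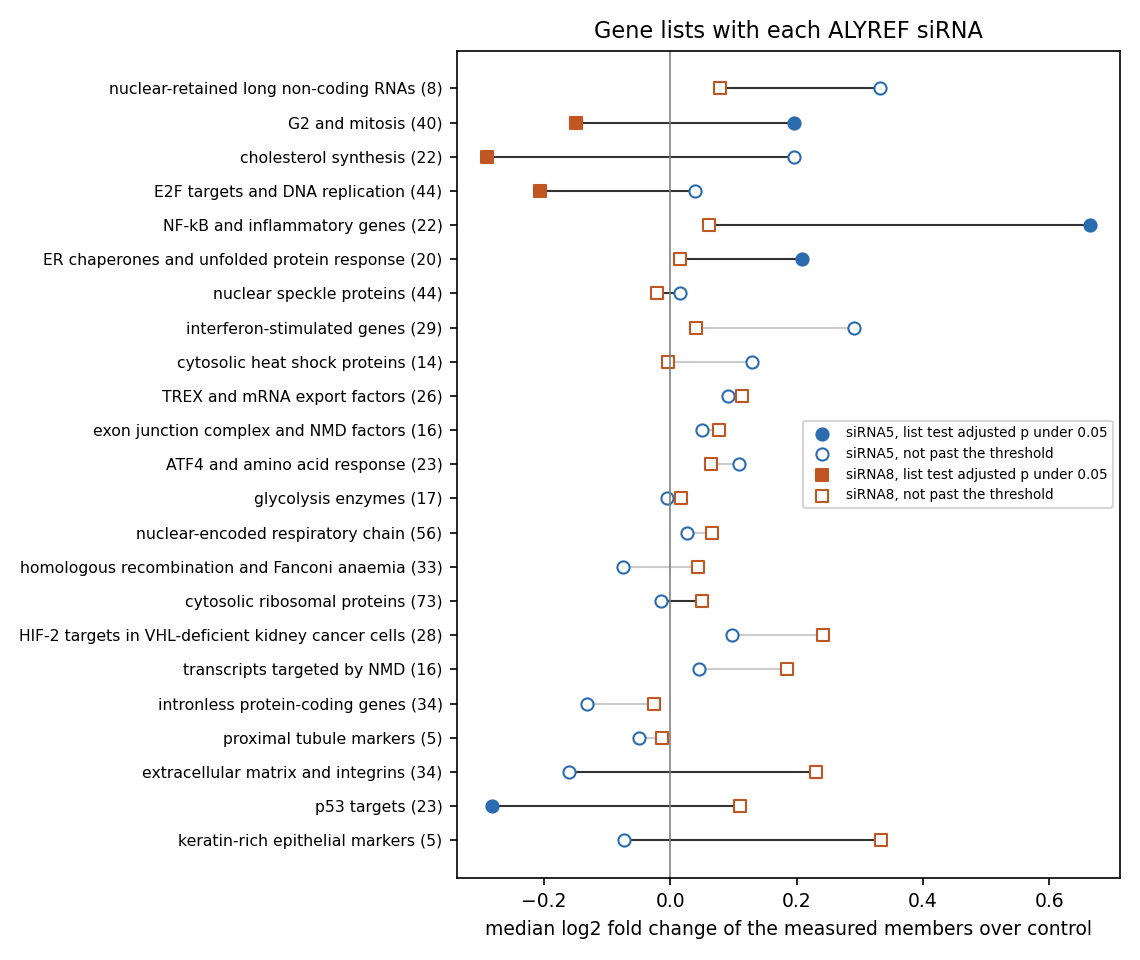
Median log2 fold change against the control of the 23 gene lists with at least 5 measured members, with siRNA5 and siRNA8 as separate points; filled points passed the list test at an adjusted p under 0.05, and a dark line joins lists that differed between the siRNAs. G2 and mitosis genes lie at 0.20 with siRNA5 and at -0.15 with siRNA8.

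The genes that changed in one direction with both siRNAs address which effects do not depend on a single ALYREF siRNA. Both comparisons share 1 non-targeting siRNA, so an effect of that control would also appear with both, and this was not tested. TMEM2, IL1RAP and PLAU rose with both, PLAU by 1.77 (SE 0.069) with siRNA5 and 1.21 (SE 0.070) with siRNA8 in the authors' deposited tables. HMGA2, a chromatin architectural protein, rose by 1.41 (SE 0.13) and 1.39 (SE 0.13), and SLC4A7, a bicarbonate transporter, rose by 1.38 (SE 0.082) and 1.23 (SE 0.082) in the authors' deposited tables. DCP2, CSGALNACT2, an enzyme of chondroitin sulfate synthesis, ADAMTS3, a procollagen-processing protease, and the tight junction gene CLDN1 also rose with both siRNAs, CLDN1 by 0.96 (SE 0.079) and 1.37 (SE 0.077) in the authors' deposited tables. H2AFX, H1FX, LSM14B and C11orf68 fell with both, H2AFX by 1.85 (SE 0.073) and 1.42 (SE 0.068) in the authors' deposited tables. The tight junction gene CLDN4 fell by 1.84 (SE 0.082) and 1.09 (SE 0.074), DOCK2, a Rac activator, by 1.45 (SE 0.12) and 1.27 (SE 0.12), and the growth factor FGF2 by 1.52 (SE 0.092) and 0.86 (SE 0.084) in the authors' deposited tables. TRNP1 and PLCE1, a phospholipase, fell with both siRNAs as well. H2AFX, DCP2, HMGA2 and LSM14B hold a 3' UTR heptamer that went with lower levels under siRNA8, and LSM14B and SLC4A7 hold one that went with lower levels under siRNA5.

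By the authors' deposited adjusted p-values, 1150 genes were higher and 1023 were lower with both siRNAs, where independent lists of these sizes would share 600.2 and 525.9. In 100 simulated data sets with shared controls and no effect, an average of 0 genes were higher and 0 lower in both comparisons, but since averages of 0.06 and 0.08 genes were called with siRNA5 and siRNA8 there, this gives no baseline for the overlap. Both fold changes exceeded 2-fold for 44 of the higher and 74 of the lower genes. Both comparisons used the same 2 control libraries, which cannot be divided between them, so part of the excess may come from the shared controls. Across the 11679 genes, which are not independent replicates, Pearson's r between the log2 fold changes was 0.398 and Spearman's rho was 0.380, against a simulated r of 0.489 (range 0.454 to 0.522) and rho of 0.450 from shared controls alone. With a shared control and no effect, r takes about this simulated value whatever the size of the noise. Real effects change the variance, so an r below it is no measure of how far the siRNAs agree. The covariance was 0.0919 against a simulated 0.0204 (range 0.0186 to 0.0229), a difference of 0.0715. Over genes with a mean of at least 500, ALYREF left out, r was 0.343 against a simulated 0.502, and the covariance was 0.0425 against 0.00282, a difference of 0.0397. The covariances argue against the spread of the shared control libraries, as rebuilt from the standard errors, as the whole source of the agreement. An effect of the non-targeting siRNA itself would also raise them and was not tested.

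**Figure D2:**
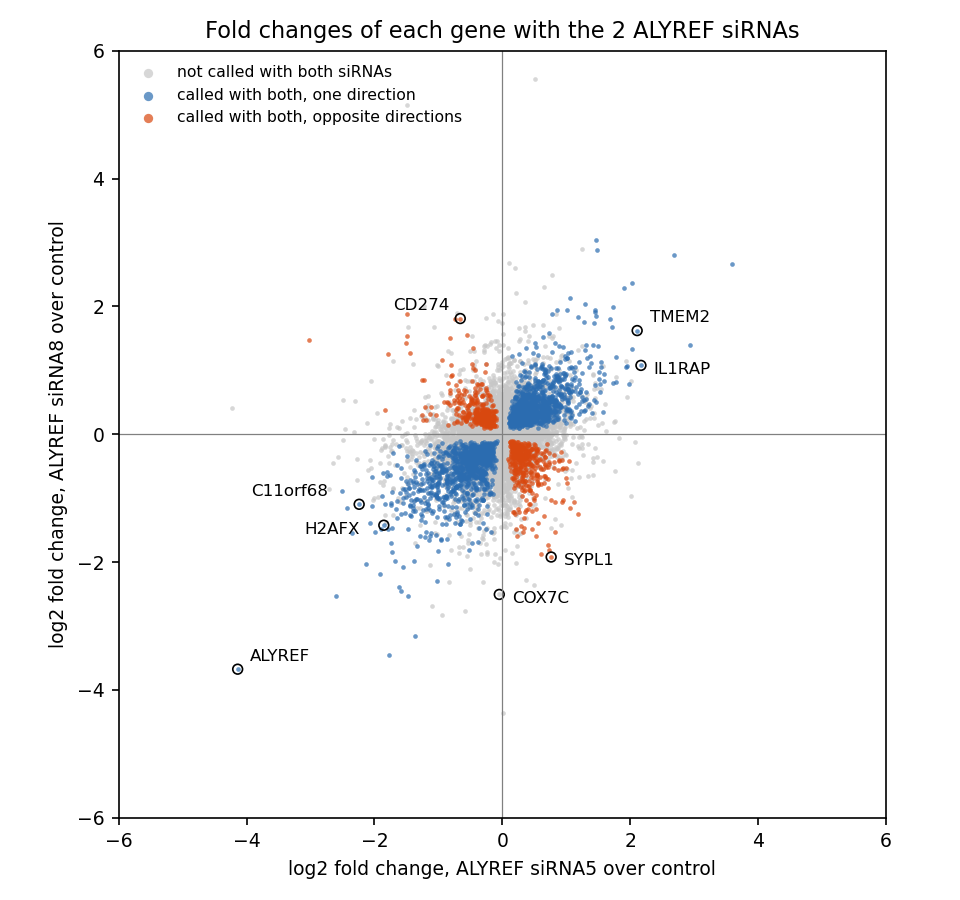
Log2 fold change against the control with siRNA5 (horizontal) and siRNA8 (vertical), 1 point per gene; colours mark genes called in one direction with both siRNAs (2173) and in opposite directions (686). ALYREF lies to the left of and below all other labelled genes.

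**Figure D3:**
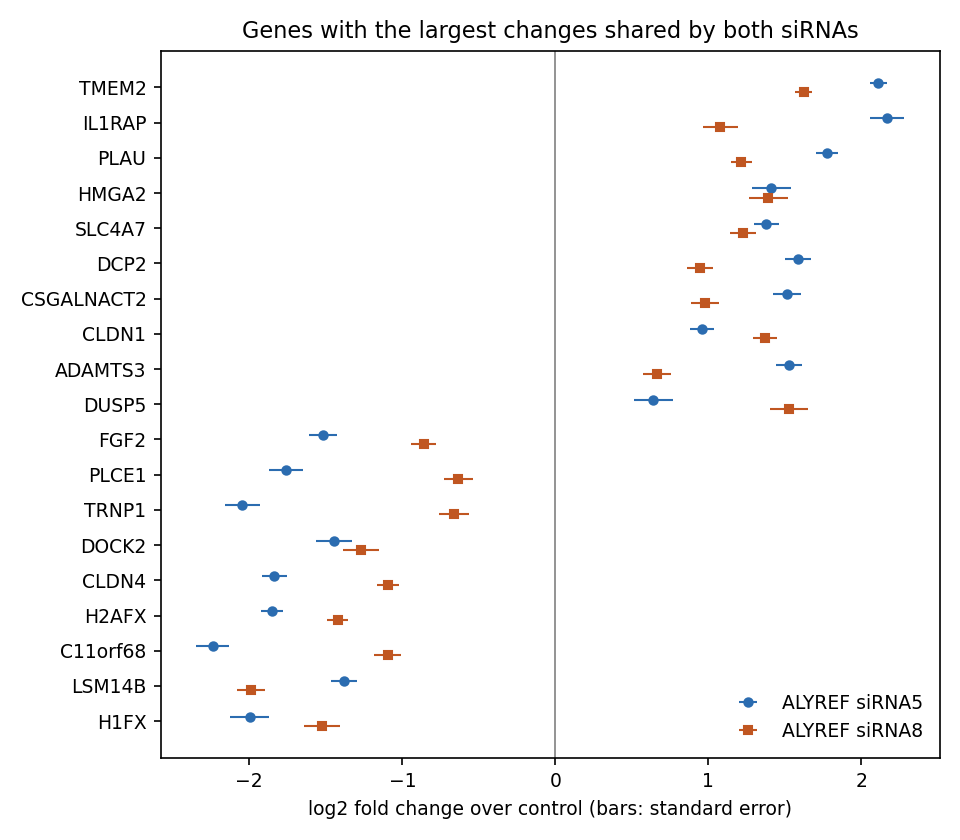
Log2 fold change against the control with each siRNA for the named genes with the largest mean rise or fall among genes called with both siRNAs, with bars of 1 SE; ALYREF is left out. TMEM2 rose by 2.11 and 1.62 and H2AFX had log2 changes of -1.85 and -1.42.

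Genes of RNA export and of nuclear speckles, the bodies in which ALYREF and splicing factors gather, were examined with both siRNAs. Of the 26 measured TREX and mRNA export factors, 10 rose, 3 fell and 13 were not called with siRNA5, and 7 rose, 2 fell and 17 were not called with siRNA8, the same counts as when adjusted over the list alone. The list test gave adjusted p = 0.204 and 0.12. The export helicase DDX39A rose by 1.03 (SE 0.056) and 0.49 (SE 0.057), and CHTOP, another export adaptor, rose by 0.72 (SE 0.063) and 0.35 (SE 0.064) in the authors' deposited tables. THOC1, a subunit of the THO complex, rose by 0.26 (SE 0.095) with siRNA5, and the export receptor NXF1 had log2 changes of -0.06 (SE 0.077) and -0.03 (SE 0.076) in the authors' deposited tables. Of the 44 measured nuclear speckle genes, 17 rose, 5 fell and 22 were not called with siRNA5 (19 and 5 adjusted over the list alone; list test adjusted p = 0.149), and 10 rose, 11 fell and 23 were not called with siRNA8 (10 and 12; adjusted p = 0.882). SRRM2, a speckle scaffold, rose by 0.37 (SE 0.044) and 0.16 (SE 0.044), and SON, the other scaffold, rose by 0.42 (SE 0.039) with siRNA5 and had a log2 change of 0.05 (SE 0.039, adjusted p = 0.28) with siRNA8 in the authors' deposited tables. The kinase DYRK1A rose by 1.09 (SE 0.095) and 0.67 (SE 0.096), and CCNL2, cyclin L2, fell by 0.46 (SE 0.061) and 0.40 (SE 0.060) in the authors' deposited tables.

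Factors and targets of nonsense-mediated decay (NMD), the pathway that degrades transcripts with early stop codons, changed in both directions. Of the 16 exon junction complex and NMD factors, 3 rose, 3 fell and 10 were not called with siRNA5 (1 and 2 adjusted over the list alone; list test adjusted p = 0.78), and 6 rose, 3 fell and 7 were not called with siRNA8 (6 and 3; adjusted p = 0.493). MAGOHB, an exon junction core protein, rose by 0.46 (SE 0.084) and 0.33 (SE 0.084), and the NMD endonuclease SMG6 fell by 0.43 (SE 0.098) and 0.23 (SE 0.095) in the authors' deposited tables. Of the 16 NMD target transcripts, 4 rose, 2 fell and 10 were not called with siRNA5 (3 and 2 adjusted over the list alone; list test adjusted p = 0.78), and 8 rose, 3 fell and 5 were not called with siRNA8 (8 and 3; adjusted p = 0.168). The snoRNA host gene SNHG15 rose by 0.48 (SE 0.13) and 0.58 (SE 0.13), and the co-chaperone DNAJB2 fell by 0.89 (SE 0.086) and 0.27 (SE 0.080) in the authors' deposited tables. Of the 34 measured intronless protein-coding genes, 7 rose, 16 fell and 11 were not called with siRNA5 (7 and 17 adjusted over the list alone; list test adjusted p = 0.132), and 8 rose, 10 fell and 16 were not called with siRNA8 (8 and 10; adjusted p = 0.739). This list holds H2AFX and H1FX, which fell, as well as the transcription factor gene JUN, which rose by 0.21 (SE 0.058) with each siRNA in the authors' deposited tables. It also holds CLDN4, which has 2 exons in the annotation used here, so the list is not strictly intronless. Its test therefore does not speak for single-exon genes as a class. The 197 annotated single-exon genes had median log2 changes of -0.28 with siRNA5 and -0.13 with siRNA8, not adjusted for GC content. Of the 8 measured nuclear-retained long non-coding RNAs, 4 rose, 1 fell and 3 were not called with siRNA5 (4 and 1 adjusted over the list alone; list test adjusted p = 0.132), and 1 rose, 2 fell and 5 were not called with siRNA8 (0 and 2; adjusted p = 0.962). NEAT1, the scaffold RNA of paraspeckles, fell by 0.84 (SE 0.11) and 1.33 (SE 0.11), and MALAT1, a speckle RNA, rose by 0.18 (SE 0.065) with siRNA5 and fell by 0.28 (SE 0.066) with siRNA8 in the authors' deposited tables.

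The hypoxia genes of this VHL-deficient line were a further focus, because HIF-2 drives them in clear cell renal cell carcinoma. Of the 28 measured HIF-2 targets, 13 rose, 7 fell and 8 were not called with siRNA5, and 16 rose, 7 fell and 5 were not called with siRNA8, the same counts as when adjusted over the list alone. The list test gave adjusted p = 0.234 and 0.0958, and with the preset correlation of 0.05 it gave 0.334 with siRNA8. Against random lists matched on mean level the median of 0.24 with siRNA8 passed (adjusted p = 0.00276). Those random lists make no allowance for members that vary together. CA12, a carbonic anhydrase, rose by 0.91 (SE 0.055) and 0.43 (SE 0.055) in the authors' deposited tables. IGFBP3, which binds insulin-like growth factors, fell by 0.79 (SE 0.12) and 0.88 (SE 0.12), and the prolyl hydroxylase EGLN3 fell by 0.21 (SE 0.088) and 0.46 (SE 0.088) in the authors' deposited tables. EPAS1, which encodes HIF-2 alpha, rose by 0.33 (SE 0.069) and 0.53 (SE 0.068) in the authors' deposited tables. ANGPTL4, a lipase inhibitor chosen after its values were seen, had a log2 change of 0.65 (SE 0.39, adjusted p = 0.163) with siRNA5 and rose by 2.30 (SE 0.37) with siRNA8 in the authors' deposited tables. Of the 17 glycolysis enzymes, 5 rose, 4 fell and 8 were not called with siRNA5, and 4 rose, 4 fell and 9 were not called with siRNA8, the same counts as when adjusted over the list alone (list test adjusted p = 0.954 and 0.882). The glycolytic entry enzyme HK2 rose by 1.01 (SE 0.072) and 0.78 (SE 0.073), and ALDOA, aldolase A, fell by 0.29 (SE 0.042) and 0.12 (SE 0.042) in the authors' deposited tables.

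Direct comparison of the siRNAs tested how far their effects differed. CD274 fell by 0.66 (SE 0.12) with siRNA5 and rose by 1.81 (SE 0.10) with siRNA8 in the authors' deposited tables, a difference of -2.47 (adjusted p = 7.13e-53). LCP1, an actin-bundling protein, fell by 0.95 (SE 0.058) and rose by 1.17 (SE 0.053), and SERINC2, a membrane protein, fell by 1.83 (SE 0.084) and rose by 0.38 (SE 0.069) in the authors' deposited tables. SYPL1 rose by 0.76 (SE 0.051) with siRNA5 and fell by 1.92 (SE 0.063) with siRNA8 in the authors' deposited tables, a difference of 2.68 (adjusted p = 2.15e-235). The guidance cue SEMA3C rose by 0.73 (SE 0.053) and fell by 1.81 (SE 0.060), and the matrix glycoprotein THBS1 rose by 0.83 (SE 0.067) and fell by 1.53 (SE 0.068) in the authors' deposited tables. TVP23B, a Golgi protein, rose by 0.72 (SE 0.11) and fell by 1.73 (SE 0.13) in the authors' deposited tables. COX7C, SEMA3C, TVP23B and THBS1 hold in their 3' UTR the heptamer that went with lower levels under siRNA8. By a normal test of the difference of the deposited fold changes, 2008 genes were higher and 1731 lower with siRNA5 than with siRNA8, 32.0% of all genes. In all, 379 genes rose with siRNA5 and fell with siRNA8 and 307 did the reverse, so that 686 of the 2859 genes called with both (24.0%) went in opposite directions. Independent lists of these sizes would give 583.4 and 541.1 such genes, more than the 379 and 307 found. Of the 4552 genes called with 1 siRNA alone, 2373 (52.1%) differed between the siRNAs. The standard error used here leaves out the covariance from the shared controls and is an upper bound, and with the control variance rebuilt from the tables the counts were 2903 and 2712.

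The lists moved apart as well, and 11 of the 23 tested lists differed between the siRNAs. Mitotic genes stood higher with siRNA5 than with siRNA8 by a median of 0.32 (list test adjusted p = 7.92e-07), and 11 of the 40 rose with siRNA5 and fell with siRNA8 or the reverse. ANLN, a cytokinesis protein chosen after its values were seen, rose by 0.44 (SE 0.044) with siRNA5 and fell by 0.32 (SE 0.045) with siRNA8 in the authors' deposited tables. Among E2F targets, with 12 members higher, 10 lower and 22 not called with siRNA5 (13 and 10 adjusted over the list alone; list test adjusted p = 0.756), the median difference was 0.25 (adjusted p = 1.83e-04). Cholesterol genes differed by a median of 0.31 (adjusted p = 0.00285), and with siRNA5 11 of them rose, 5 fell and 6 were not called (11 and 6 adjusted over the list alone; list test adjusted p = 0.234). INSIG1, a sterol sensor chosen after its values were seen, rose by 0.37 (SE 0.14) with siRNA5 and fell by 0.54 (SE 0.14) with siRNA8 in the authors' deposited tables. The p53 targets were lower with siRNA5 by a median of -0.38 (adjusted p = 1.51e-04), and with siRNA8 8 rose, 3 fell and 12 were not called (9 and 3 adjusted over the list alone; list test adjusted p = 0.361). CDKN1A rose by 0.22 (SE 0.087) with siRNA8 in the authors' deposited table. GDF15, a stress cytokine with a low mean of 50.9, rose by 2.49 (SE 0.40) with siRNA8 in the authors' deposited table and was chosen after its values were seen.

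Genes of the extracellular matrix, inflammation and protein folding also separated the siRNAs. Of the 34 measured extracellular matrix and integrin genes, 7 rose, 16 fell and 11 were not called with siRNA5 (9 and 16 adjusted over the list alone; list test adjusted p = 0.126), and 15 rose, 6 fell and 13 were not called with siRNA8 (16 and 6; adjusted p = 0.0958). Against matched random lists both medians passed (adjusted p = 0.0147 and 0.0023), as they did in the list test without heptamer genes (adjusted p = 0.0382 and 0.0222). The random lists make no allowance for correlation between genes, and with the preset of 0.05 the list test gave adjusted p = 0.317 and 0.334. The median difference between the siRNAs was -0.33 (adjusted p = 1.51e-04). Fibronectin, FN1, rose by 0.26 (SE 0.080) and 1.26 (SE 0.080), and COL6A1, a collagen VI chain, fell by 0.48 (SE 0.099) and 1.70 (SE 0.11) in the authors' deposited tables. NF-kB genes differed by a median of 0.25 (adjusted p = 0.028), a call lost with the preset correlation of 0.05 (adjusted p = 0.128), and with siRNA8 5 rose, 4 fell and 13 were not called (5 and 4 adjusted over the list alone; list test adjusted p = 0.882). The cytokine LIF rose by 0.80 (SE 0.050) and 0.80 (SE 0.049) in the authors' deposited tables. ER chaperone genes differed by 0.19 (adjusted p = 0.00632), a call lost on log2 fold changes (adjusted p = 0.204), and with siRNA8 9 rose, 4 fell and 7 were not called (9 and 4 adjusted over the list alone; list test adjusted p = 0.791). Nuclear speckle genes differed by 0.13 (adjusted p = 0.0036), with 15 members higher and 1 lower with siRNA5 than with siRNA8, and the preset correlation of 0.05 (adjusted p = 0.0628) and log2 fold changes (adjusted p = 0.256) end this call. Among them BCLAF1 and THRAP3, a related pair of splicing-linked proteins chosen after their values were seen, rose by 0.71 (SE 0.051) and 0.61 (SE 0.044) with siRNA5 and by 0.38 (SE 0.052) and 0.34 (SE 0.044) with siRNA8 in the authors' deposited tables. Nuclear-retained RNAs differed by 0.34 (adjusted p = 0.0274), a call lost with the preset correlation of 0.05 (adjusted p = 0.0628). KCNQ1OT1, an imprinting RNA chosen after its values were seen, rose by 1.82 (SE 0.20) with siRNA5 and had a log2 change of -0.06 (SE 0.21) with siRNA8 in the authors' deposited tables. Of the 11 lists, 7 also differed with the preset correlation of 0.05 and 8 on log2 fold changes without ranks.

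The remaining lists did not pass the list test on the Wald statistic with either siRNA. Of the 73 measured ribosomal protein genes, 0 rose, 7 fell and 66 were not called with siRNA5 (0 and 3 adjusted over the list alone; list test adjusted p = 0.343), and 13 rose, 5 fell and 55 were not called with siRNA8 (10 and 4; adjusted p = 0.167). The median difference was -0.06 (adjusted p = 0.0232), a call lost with the preset correlation of 0.05 (adjusted p = 0.205) and on log2 fold changes (adjusted p = 0.765). RPL22 rose by 0.26 (SE 0.052) and RPL10 fell by 0.28 (SE 0.055) with siRNA8 in the authors' deposited table. Of the 56 respiratory chain genes, 6 rose, 8 fell and 42 were not called with siRNA5, and 14 rose, 7 fell and 35 were not called with siRNA8, the same counts as when adjusted over the list alone (list test adjusted p = 0.97 and 0.184). SDHA, a succinate dehydrogenase subunit, fell by 0.19 (SE 0.048) and 0.19 (SE 0.047) in the authors' deposited tables. Of the 33 homologous recombination and Fanconi anaemia genes, 7 rose, 8 fell and 18 were not called with siRNA5 (8 and 8 adjusted over the list alone; list test adjusted p = 0.763), and 5 rose, 6 fell and 22 were not called with siRNA8 (5 and 6; adjusted p = 0.991). The repair genes BRCA1 and FANCD2 fell by 0.55 (SE 0.083) and 0.51 (SE 0.081) with siRNA5 and by 0.42 (SE 0.082) and 0.37 (SE 0.079) with siRNA8 in the authors' deposited tables. Of the 29 measured interferon-stimulated genes, 9 rose, 3 fell and 17 were not called with siRNA5, and 4 rose, 5 fell and 20 were not called with siRNA8, the same counts as when adjusted over the list alone (list test adjusted p = 0.132 and 0.991). With siRNA5 this list passed on log2 fold changes (adjusted p = 0.0484) and against matched random lists (adjusted p = 0.0147). The random lists make no allowance for correlation between genes, and with the preset of 0.05 the list test gave adjusted p = 0.317 with siRNA5. SAMD9L, an antiviral factor, rose by 1.20 (SE 0.19) and 0.48 (SE 0.20), and ISG15, a ubiquitin-like modifier, fell by 0.87 (SE 0.13) and 0.99 (SE 0.13) in the authors' deposited tables.

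Of the 23 measured ATF4 and amino acid response genes, 9 rose, 1 fell and 13 were not called with siRNA5, and 7 rose, 4 fell and 12 were not called with siRNA8, the same counts as when adjusted over the list alone (list test adjusted p = 0.126 and 0.739). ASNS, asparagine synthetase, rose by 0.52 (SE 0.11) and 0.30 (SE 0.11) in the authors' deposited tables. Of the 14 measured cytosolic heat shock genes, 7 rose, 2 fell and 5 were not called with siRNA5, and 4 rose, 2 fell and 8 were not called with siRNA8, the same counts as when adjusted over the list alone (list test adjusted p = 0.149 and 0.899). The co-chaperone DNAJB1 rose by 0.32 (SE 0.055) and 0.23 (SE 0.055), and the small heat shock gene HSPB1 fell by 0.17 (SE 0.054) and 0.32 (SE 0.054) in the authors' deposited tables. Among housekeeping genes, ACTB, beta-actin, had log2 changes of -0.07 (SE 0.046) and -0.02 (SE 0.046), and GAPDH, a glycolytic enzyme, fell by 0.13 (SE 0.049) with siRNA5 and had a log2 change of -0.05 (SE 0.049) with siRNA8 in the authors' deposited tables. In 8 of the 46 list results the median, the mean and the test differed in sign, and 0 of these passed the threshold.

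Markers of other cell types were few. Of the listed markers, 5 of 17 proximal tubule genes, 2 of 14 immune genes, 0 of 10 endothelial genes and 5 of 14 keratin-rich epithelial genes were measured, and 0 of 13 mitochondrially encoded genes were in the tables. The tubule gene PAX2, a kidney transcription factor, rose by 0.61 (SE 0.13) with siRNA5 and had a log2 change of -0.01 (SE 0.13) with siRNA8 in the authors' deposited tables. In this list 2 genes rose, 1 fell and 2 were not called with siRNA5 (2 and 2 adjusted over the list alone; list test adjusted p = 0.918), and 1 rose, 0 fell and 4 were not called with siRNA8 (1 and 0; adjusted p = 0.882). The macrophage receptor gene CSF1R, with a mean of 60.8, fell by 0.77 (SE 0.31) with siRNA5 in the authors' deposited table, and it was the 1 immune marker called with either siRNA, with or without adjustment over the list alone. Among the keratin-rich markers, 0 rose, 2 fell and 3 were not called with siRNA5 (list test adjusted p = 0.149), and 3 rose, 0 fell and 2 were not called with siRNA8 (adjusted p = 0.12), the same counts as when adjusted over the list alone. They differed by a median of -0.75 (adjusted p = 0.0102). The keratin gene KRT19 fell by 1.77 (SE 0.13) with siRNA5, and KRT18 rose by 0.68 (SE 0.061) with siRNA8 in the authors' deposited tables. Values of TVP23B, DDX39A, MAGOHB, KRT18, RPL22, RPL10 and COX7C are uncertain, because each gene has close paralogs or processed copies elsewhere in the genome. Besides the genes already named for it, DYRK1A, MAGOHB, CA12, BRCA1, COL6A1, SON and BCLAF1 hold in their 3' UTR the heptamer that went with lower levels under siRNA8, and COL6A1 and FDFT1 hold the one that went with lower levels under siRNA5.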

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

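Of the tests here, the heptamer scan and its test of base composition, the search of the ALYREF transcript and the GC test on the difference between siRNAs were chosen after the result was seen, as was the test of the difference between the siRNAs. That last test, which sets the 2 log2 fold changes against their standard errors, picked out the differences between the siRNAs. The heptamers came from the scan, and the GC trend from correlations within each comparison.

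With siRNA5, 2008 genes were higher and 1731 lower than with siRNA8, and 686 genes were called in opposite directions. Among the 114 genes named by rule, 56 differed, where 32.0% of all genes did. The rule takes some of these genes for this same difference or for large changes, so the count is no evidence about them. ALYREF itself was lower with siRNA5 by a log2 difference of -0.47. Among genes in the upper part by mean level, those furthest below their siRNA8 level were CD274 (-2.47), SERINC2 (-2.21), LCP1 (-2.12), DUSP10 (-2.10) and HMOX1 (-2.03). In the same part, those furthest above it were SYPL1 (2.68), SEMA3C (2.54), COX7C (2.46), TVP23B (2.45) and THBS1 (2.36). Lists that stood higher with siRNA5 by the list test were nuclear speckle proteins (median difference 0.13), E2F targets (0.25), G2 and mitosis (0.32), ER chaperones (0.19), NF-kB genes (0.25), cholesterol synthesis (0.31) and nuclear-retained RNAs (0.34). Lists that stood lower were p53 targets (-0.38), extracellular matrix (-0.33), ribosomal proteins (-0.059) and keratin-rich epithelial markers (-0.75). With a preset correlation of 0.05 the calls for speckle proteins (adjusted p = 0.0628), NF-kB genes (adjusted p = 0.128), nuclear-retained RNAs (adjusted p = 0.0628) and ribosomal proteins (adjusted p = 0.205) were lost, and on log2 fold changes those for speckle proteins (adjusted p = 0.256), ER chaperones (adjusted p = 0.204) and ribosomal proteins (adjusted p = 0.765).

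Of 16135 heptamers in 3' UTRs, AACGCTG had the lowest score with siRNA5 (z -7.89, and -1.14 with siRNA8), where 41.9% of its 313 genes were called lower against 21.9% of the others, and ACTAGAA the lowest with siRNA8 (z -12.2, and 1.30 with siRNA5), where 35.1% of its 1196 genes were called lower against 19.2%. As a set, the other orderings of the same bases did not go with lower levels. Genes with them had a median shift of 0.023 (95% interval 0.020 to 0.027) with siRNA5 and 0.031 (0.028 to 0.034) with siRNA8. The heptamers' own shifts were -0.21 and -0.15, and the lowest of the other orderings reached -0.17 and -0.12. Because the heptamers were picked as the lowest of the scan, their gap to the median ordering was fixed in advance. That gap cannot decide whether base composition of the 3' UTR is the cause. Genes with the 3' UTR site lay below genes with a site in the coding sequence alone by -0.097 (SE 0.034) with siRNA5 and -0.089 (SE 0.022) with siRNA8, as a seed match acting through the 3' UTR needs, but coding-only genes were lower as well (-0.10, SE 0.021, and -0.07, SE 0.016) and the heptamers were picked by their 3' UTR score. Both heptamers (2 of 2) occur in the ALYREF coding sequence, which 5.94% of heptamers do by being somewhere in its transcript, so a candidate explanation is a seed match of the transfected siRNA to untargeted transcripts. This is a hypothesis, because the siRNA sequences are not given in the sources used here.

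Cell cycle, cholesterol and p53 lists moved apart between the siRNAs, and 24.0% of the genes called with both went in opposite directions. Unequal depth of ALYREF knockdown alone, if it changes the size of an effect and not its direction, is argued against for the 686 genes called in opposite directions. Knockdown left 5.67% of ALYREF with siRNA5 and 7.83% with siRNA8. For differences within one direction unequal depth stays open, because no test here separates it from the siRNA used. Sites of these 2 heptamers in the 3' UTRs of the list genes are argued against as the whole cause. All 4 lists (E2F, G2 and mitosis, cholesterol, p53) kept their difference without genes that hold either heptamer. Genes with an overlapping heptamer, such as CTAGAAA (z -11.5 with siRNA8, 1692 genes), or with coding sites alone were not removed on that ground. Other sites of this kind therefore stay open. Effects that begin at a heptamer gene and spread to these lists, and differences between libraries of a group, stay open, and a biological difference between the siRNAs was not tested.

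Fold changes fell with the GC content of the transcript in both comparisons, with a Spearman rho across genes, which are not independent replicates, of -0.27 with siRNA5 and -0.18 with siRNA8. GC bias of the shared control libraries alone is argued against, because the difference between the siRNAs, in which the controls cancel, also followed GC (rho -0.11, 95% interval -0.13 to -0.09). Few exons in GC-rich genes are argued against by the trend over genes with more than 8 exons (rho -0.24 for the mean fold change). A GC bias that differs between the library groups stays open, as does a dependence of GC-rich transcripts on ALYREF, which would be a hypothesis. With the trend removed, 1036 genes were higher and 979 lower with both siRNAs, where the same genes as deposited gave 1139 and 971.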

How the results depend on the processing

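The alternatives added after the data were seen were the repeat without counters, centring, the repeat without heptamer genes, the rebuilt standard error and the other list tests. Of 94 main results under alternatives, 75 kept their direction and stayed within 1.5 times their value for counts, or within their 95% interval for the correlation, 19 moved further, and 0 were reversed. Of the 75, 30 had exactly the reported value, among them the ALYREF levels, which only centring can move here and which say nothing about stability. A fold limit of 2 moved most counts, as its construction takes fewer genes: 193 genes higher and 363 lower with siRNA5, 183 and 320 with siRNA8, 44 and 74 with both, 9 in opposite directions, 270 and 245 between the siRNAs, a correlation of 0.43 and 0 and 0 lists for siRNA5 and siRNA8. At adjusted p 0.01 the genes in opposite directions were 423, also by construction. Without genes holding either heptamer the correlation was 0.42. Each heptamer was picked for genes lower with 1 siRNA, and its score with the other was much nearer to none. Leaving these genes out therefore favours a higher correlation by construction, and how much of the rise this accounts for was not tested. With the control variance rebuilt, 2712 genes were lower with siRNA5 than with siRNA8 (2903 higher), since the standard error is smaller. The lists called with siRNA8 were 0 on log2 fold changes, 1 with a preset correlation of 0.05 and 5 against matched random lists, and those with siRNA5 were 0 with the correlation of 0.05; the cause was not tested. Of 258 values of named genes, 31 lost their call at adjusted p 0.01, 168 at the 2-fold limit and 1 (TUG1 with siRNA8) when centred. No paired analysis was possible because the tables hold no values per library. For the same reason the planned size factors, no scaling, no filter, other tool, 4-library fit, replicate block, leave-one-out, pseudocount, fry and estimated correlation were not run. Depth limits calls at low means: 17.4% of genes under a mean of 50 were called with siRNA5, against 59.0% at 500 or more.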

Other observations

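Genes with few exons were lower with both siRNAs. The 197 single-exon genes had a median log2 change of -0.28 (95% interval -0.37 to -0.23) with siRNA5 and -0.13 (-0.21 to -0.03) with siRNA8, and 80 and 57 of them fell while 19 and 20 rose. Genes with 2 exons (476) had medians of -0.14 and -0.08, and the 5999 genes with more than 8 exons had 0.03 and 0.03. Median GC content was 51.5% in single-exon genes and 47.7% in genes with more than 8 exons. These medians were not adjusted for GC content, and their intervals come from resampling genes, without the spread between libraries.

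Genes in the lowest decile of transcript GC content had median log2 changes of 0.19 with siRNA5 and 0.06 with siRNA8, and those in the highest decile -0.16 and -0.16. Genes higher with siRNA5 had a median GC content of 44.2% against 48.5% in genes matched on mean level, and genes lower with siRNA5 had 53.1% against 48.5%. With siRNA8 the medians were 46.0% against 48.1% for higher genes and 51.0% against 48.0% for lower genes. Transcripts higher with siRNA5 had a median length of 3932 nt against 3033 nt in matched genes, and those lower had 3283 nt against 2992 nt. With siRNA8 the medians were 3662.5 nt against 3168.5 nt for higher and 3339 nt against 3199 nt for lower genes.

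Among 3' UTR heptamers, the highest scores with siRNA5 belonged to the AU-rich sequences TTACAAA (z 5.87) and TATTTAT (z 5.84), and TTACAAA was also the highest with siRNA8 (z 5.01). Of the genes that rose with siRNA5 and fell with siRNA8, 31.0% hold the siRNA8 heptamer, against 16.1% of the other genes called lower with siRNA8. Of the genes that fell with siRNA5 and rose with siRNA8, 5.35% hold the siRNA5 heptamer, against 5.40% of the other genes called lower with siRNA5. These shares were not adjusted for UTR length or base composition. Genes with the siRNA8 heptamer already had a median log2 change of 0.099 with siRNA5, against 0.006 for genes without it. A rise with siRNA5 therefore favours genes that hold it, and the 31.0% does not separate an effect of the site from this. These scans were chosen after the data were seen.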
